A study of Bos taurus with 11 samples.

How the data were processed

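Gene expression was measured by RNA sequencing in bovine (Bos taurus) trophectoderm, the outer epithelium of the embryo from which the fetal part of the placenta grows. The labels give 11 libraries in 2 groups. Day 8 holds 4 libraries from embryos produced in vitro, and day 15 holds 7 libraries from conceptuses collected in pregnancy after transfer of such embryos. The series title names culture conditions as the topic, but no label gives a condition for a library, so none was compared. Per the labels' protocols, day-15 RNA was extracted with Trizol and a column and its concentration was measured, while day-8 RNA was purified on a PicoPure column and was too little to measure. The 2 days also carry different library series numbers. Day, extraction, library series and growth in culture or in the uterus therefore change together and cannot be told apart. Per the labels' protocols, full-length cDNA was made from polyA RNA with a low-input template-switching kit starting from 4 ng of total RNA, and libraries were made by tagmentation, a method that does not keep the strand. The labels give a read length of 50 bases.

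The submitters' processing notes name bcl2fastq 2.17.1.14, fastp 0.20.1, TopHat2 2.1.1 and Bowtie2 2.3.4.1, and the genome build ARS-UCD1.2. The authors deposited 1 table of raw read counts per gene, with whole numbers and no normalization, beside each gene's exon positions and exonic length. The counting program, the annotation release, the strand setting and the handling of reads that match several places are not given in the sources used here. How reads were divided between near-identical genes, overlapping genes or antisense pairs is therefore uncertain. The table lists 27270 genes on 31 chromosomes, of which 6831 have no count in any library. Each of the 11 count columns matches 1 library by its name, and 0 count columns were left unused. For most columns the match holds only once a serial number within the library name is left out.

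Genes carry Ensembl identifiers without symbols. The RefSeq gene table at hand describes another assembly (ARS-UCD2.0), and 0 of the 27270 identifiers matched it, so no gene was named and at most 2 identifiers per direction are printed. The gene lists, cell type markers and gene panel fixed before the data were examined, the family and ribosomal shares of counts, and the alternatives that need gene families or GC content were not run for this reason. Markers of other cell types were thus not analysed here. In their place, groups of genes were formed from the table's own coordinates after the data were first read. These are windows of 1 Mb (by gene midpoint, at least 5 tested genes), and 4 classes by number of merged exons (1, 2 to 5, 6 to 15, over 15). Genes on at 1 day alone (at least 1 CPM in each library of that day and under 0.1 CPM in each library of the other) and neighbouring genes that change together were also added then. Chromosomes (at least 20 tested genes) were planned before the data were examined, as were the tests of single genes between the days and between title numbers, of shares of counts and of spread. The plan for the mitochondrial share named encoded genes by symbol, and all 37 mitochondrial features were used instead. The share of mitochondrial features under 100 bases was not in that plan. Coordinates are those of the deposited table.

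Computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr at its default settings, TMM factors were applied, and edgeR's quasi-likelihood test compared day 15 with day 8 over 11 libraries, and the higher with the lower title number over the 7 day-15 libraries. A title number follows the day in each day-15 title and takes 1 of 2 values, whose meaning the labels do not give. It was treated as a possible batch. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Sets of genes were tested with limma's camera on voom values with the preset inter-gene correlation of 0.01, two-sided, adjusted within each family of sets. An estimated correlation and fry were alternatives. Shares of counts and genes detected after thinning each library to the smallest total were compared by an exact two-sided permutation test over all 330 splits of the libraries into 4 and 7. CPM values are TMM-normalised, with some exceptions. Library totals alone scale the definition and levels of genes on at 1 day alone, and a filter of 5 CPM used as an alternative. They also scale the CPM limits and levels in the tests of day-15 replicate 1. Spread is edgeR's common dispersion, given as the biological coefficient of variation. Identifiers named in the text are the 2 largest rises and 2 largest falls among called genes with a mean log2 CPM of at least 4 and CPM ranges that do not overlap between days. This is the rule written before the data were examined, without its conditions on gene symbols.

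Library totals ran from 46152663 to 92463564 counts. At the smallest total, 3 counts equal 0.065 CPM, which is the limit a count of 0 allows. Such limits cover counting error only, since amplified reads are not independent molecules. The titles number the embryos or conceptuses separately, but no label states that each library is another animal, so p-values measure the spread between these libraries. The day-8 titles all share a code whose meaning the labels do not give. Whether the day-8 libraries come from a single batch is therefore unknown. No pair of libraries of 1 day agreed within sampling noise (lowest chi-square of 78.5 per gene). The scripts were tested on simulated counts with 200 changed genes. For day 15 against day 8, 61.5% of genes changed 4-fold and 90.5% of genes changed 8-fold were called, over 14028 and 14004 genes. For the title-number comparison, the shares were 37.5% at 4-fold and 86.0% at 8-fold, over 13105 and 13112 genes. Camera found the 2 windows set to change in each simulation. Simulated genes were drawn independently, and the genes of a changed window outside the 200 all shifted by the same fold. Genes in the data need not behave so, and the simulations therefore say little about camera's errors on the real windows. For the days at 8-fold it also called 2 windows that were not set to change as a whole, and at 4-fold 0.

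Alternatives were DESeq2, limma voom, DESeq2 size factors, upper-quartile factors, library totals alone, no count filter, a filter of 5 CPM, thinning, glmTreat against a 2-fold change, removal of the 50 most abundant genes, each title number alone, and leaving out each library. Alternatives added after seeing the data were a loess offset on exonic length, library quality weights in limma, removal of mitochondrial features, removal of genes whose spans overlap, other window sizes, and removal of day-15 replicates 1 and 2. The library names of these 2 replicates hold no serial number, unlike those of the other 5, so they were treated as a possible batch. Their comparison with the other 5 was also added after seeing the data.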

Results

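Transcript counts were compared between trophectoderm of day-8 in vitro bovine embryos (4 libraries) and trophectoderm of day-15 conceptuses that had grown in the uterus after transfer (7 libraries). Between these days the blastocyst hatches and the trophectoderm grows from a small sphere to a long filament, before it attaches to the uterus. Day-8 libraries held from 55960944 to 64674178 counts. Day-15 libraries held from 46152663 to 53541972 counts, except replicate 7 with 92463564. Among the day-15 libraries, 3 share the lower of 2 numbers that follow the day in their titles (replicates 1, 3 and 4) and 4 share the higher one (replicates 2, 5, 6 and 7). The labels do not say what these title numbers mean.

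The day separated the libraries along the first principal component of log2 CPM, which held 56.7% of the variance. Rank correlations across genes ran from 0.955 to 0.976 among day-8 libraries and from 0.77 to 0.863 between days. Day-15 replicate 1 stood apart from the other day-15 libraries along the second component, which held 17.2% of the variance. Its rank correlations with the other day-15 libraries were 0.878 to 0.915, while those among the other 6 were at least 0.954. Its TMM factor was 0.554, against 0.955 to 1.09 in the other day-15 libraries.

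**Figure D1:**
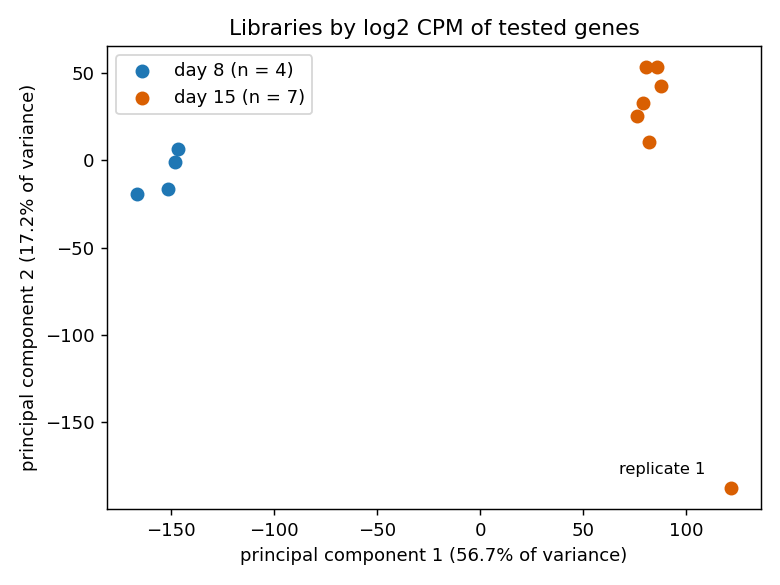
Each point is 1 library, placed by the first 2 principal components of TMM-normalised log2 CPM over the tested genes, with day 8 in blue (n = 4) and day 15 in orange (n = 7). The first component separates the days, and day-15 replicate 1 lies at -187.7 on the second component, away from the 10 other libraries.

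Day 15 against day 8, the comparison that the series' design text sets out, changed 5600 of 14278 tested genes. At day 15, 2710 genes were higher and 2890 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Changes of at least 8-fold were fitted for 641 genes that rose and 1007 that fell, and changes of at least 32-fold for 304 and 429. The median size of a called change was 1.91 on the log2 scale. CPM ranges of the 2 days did not overlap for 4399 tested genes, or 4090 of the called ones, where chance gives 0.606% of genes. Without day-15 replicate 1, 3404 genes were higher and 3659 lower. The share of called genes that rose was 48.4%, but 37.4% when libraries were scaled by their totals alone, which moved the median log2 fold change of all tested genes from 0.05 to -0.17. With an offset on exonic length it was 54.4% (3302 higher and 2768 lower), and the median was 0.15.

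Among called genes with a mean log2 CPM of at least 4 and day ranges that do not overlap, the largest rise was that of ENSBTAG00000013950, a gene of 6 exons on the plus strand of chromosome 13 (74106673 to 74114980). It held 8302 ± 3321 CPM at day 15 (SD, n = 7) and 0.343 ± 0.397 CPM at day 8 (SD, n = 4). Its day-8 libraries had between 0 and 48 counts, and its fitted log2 fold change was 14.55 (SE 1.53; edgeR adjusted p = 1.68e-05). Next came ENSBTAG00000017531, with 7 exons on the minus strand of chromosome 1 (80560914 to 80576233), at 1186 ± 497 CPM against 0.0884 ± 0.177 CPM. Its log2 fold change was 13.66 (SE 1.41; edgeR adjusted p = 1.48e-05), and 3 of the 4 day-8 libraries had no count. Fitted fold changes of both genes depend on the prior count, because the day-8 level lies near 0. Their order turned without day-8 replicate 4, with 19.05 for ENSBTAG00000017531, then without a count at day 8, and 15.03 for ENSBTAG00000013950.

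The mean log2 CPM was taken over all 11 libraries, of which 7 are of day 15. This limit therefore left out larger falls, also of genes abundant at day 8 that were near 0 at day 15. Among genes on at day 8 alone, the highest mean was 862 CPM at day 8. Under the same limits, the largest fall was that of ENSBTAG00000021829, with 4 exons on the plus strand of chromosome 7 (62495947 to 62508685). It dropped from 1434 ± 186 CPM (SD, n = 4) to 4.36 ± 2.32 CPM (SD, n = 7), a log2 fold change of -8.36 (SE 0.50; edgeR adjusted p = 2.23e-07). ENSBTAG00000008332, with 20 exons on the minus strand of chromosome 6 (14912679 to 14992464), dropped from 612 ± 115 CPM to 3.37 ± 0.964 CPM. Its log2 fold change was -7.50 (SE 0.28; edgeR adjusted p = 1.50e-08), and its span overlaps 1 other annotated gene. The 4 genes kept their direction and an adjusted p under 0.05 in each setting that tested them.

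**Figure D2:**
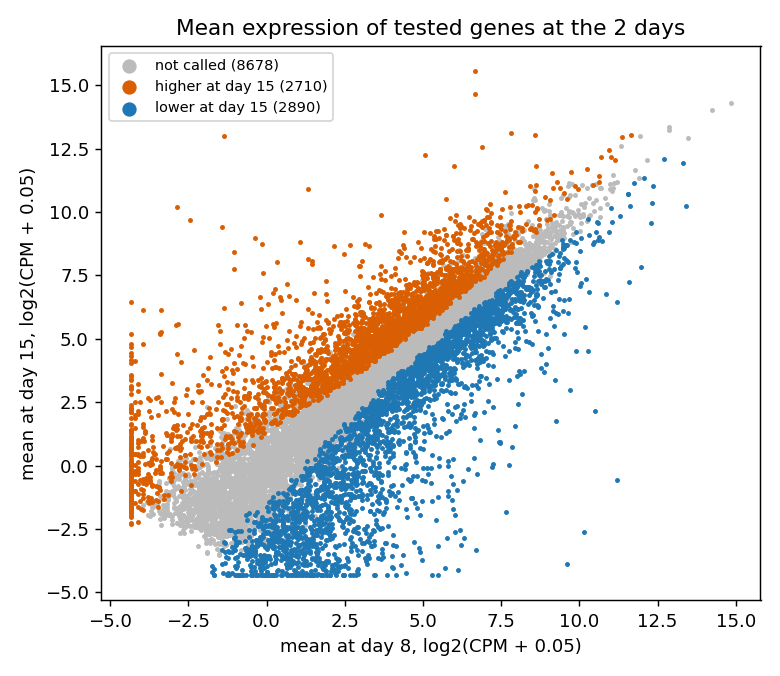
Mean CPM of each tested gene at day 15 (vertical) against day 8 (horizontal), both as log2(CPM + 0.05), with genes called higher at day 15 in orange, genes called lower in blue and other genes in grey. The 2710 orange points lie mostly above and the 2890 blue points mostly below the diagonal of equal expression.

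Among genes that neighbour each other, 1 window of 1 Mb was higher and 4 were lower at day 15, out of 1067 tested (camera, adjusted p under 0.05). None of the 5 was called with an estimated correlation (adjusted p = 0.978 for each), or without day-15 replicate 1 (adjusted p between 0.076 and 0.0819). The window that rose lies on chromosome 8 (22000001 to 23000000). Its 10 tested genes summed to 7515 ± 1785 CPM at day 15 (SD, n = 7) against 218 ± 53.8 CPM at day 8 (SD, n = 4), which is 34.5-fold. There 6 genes were called higher and 0 lower, 5 of the 10 have a single exon, and 1 gene held 64.5% of the window's CPM (camera adjusted p = 0.0215).

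The windows that fell lie on chromosomes 16, 9, 18 and 21. On chromosome 16 (54000001 to 55000000) the 6 tested genes were all called lower, with a median log2 fold change of -6.36 and a sum of 428 ± 134 CPM at day 15 against 1899 ± 174 CPM at day 8 (camera adjusted p = 0.0234). On chromosome 9 (87000001 to 88000000), 5 of 8 genes were called lower and 0 higher, and the sum was 12.6 ± 10.2 CPM against 70.5 ± 5.87 CPM (camera adjusted p = 0.0215). On chromosome 18 (64000001 to 65000000), 13 of 20 genes were called lower and 0 higher, with sums of 78.5 ± 40.6 CPM at day 15 and 172 ± 27.7 CPM at day 8 (camera adjusted p = 0.0215). On chromosome 21 (65000001 to 66000000), 8 of 13 genes were called lower and 1 higher, and 4 of the 13 have a single exon. Those called lower include short features at 65727686 to 65727790 and at 65796122 to 65796229. That window summed to 437 ± 123 CPM against 806 ± 96.1 CPM, and 1 gene held 71.3% of it (camera adjusted p = 0.0234). Without day-15 replicate 1 each of the 5 windows kept its direction.

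**Figure D3:**
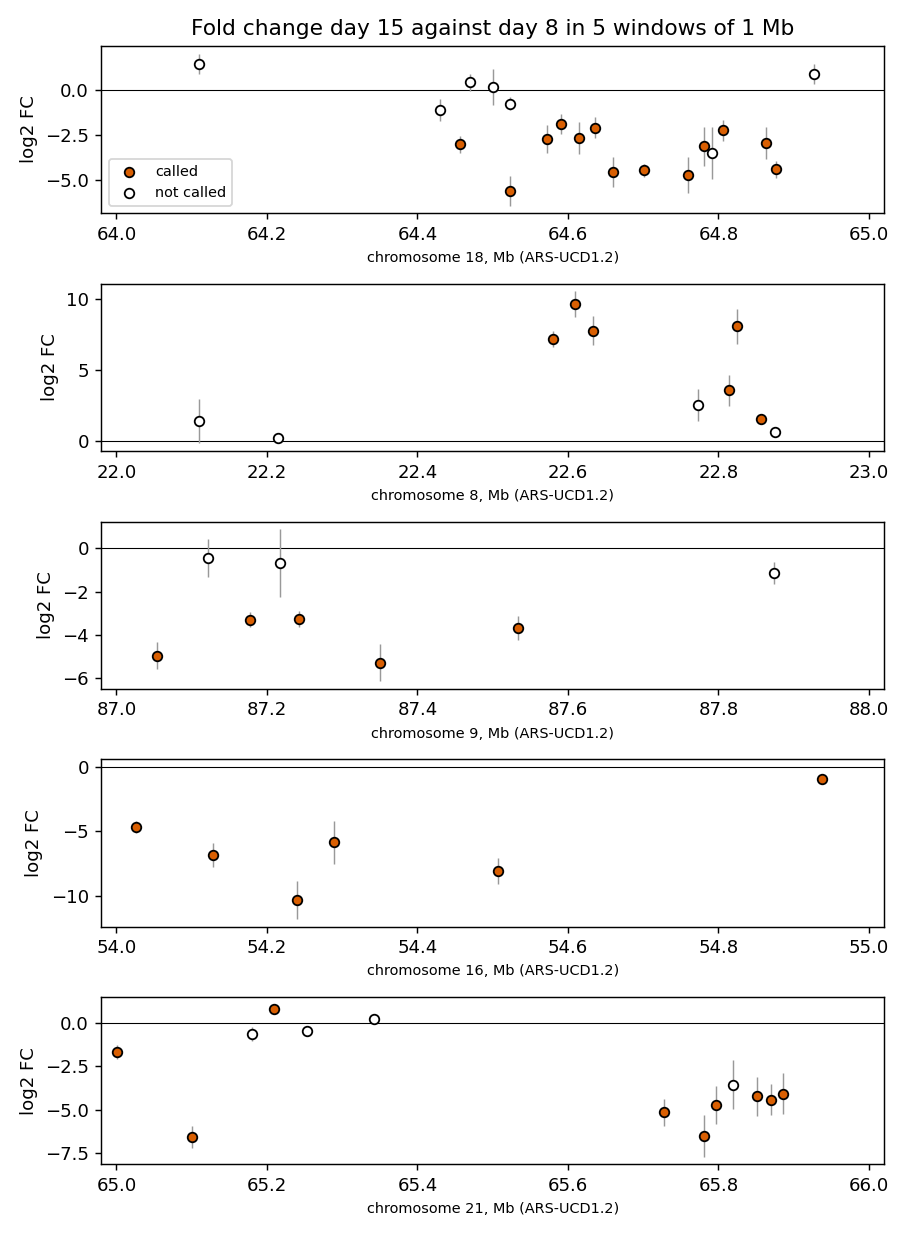
Fitted log2 fold change (day 15 against day 8, bars give the SE) of each tested gene in the 5 called windows, placed by its midpoint in Mb on build ARS-UCD1.2, with called genes filled. In the window on chromosome 8 the fold changes range from 0.17 to 9.62, and in that on chromosome 16 from -10.35 to -0.92.

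No chromosome was called as moving differently from the other genes (camera, 0 of 31 at adjusted p under 0.05, and 0 at an unadjusted p under 0.05). On the X chromosome 87 genes were called higher and 106 lower among 500 tested, with a median log2 fold change of -0.13 (camera adjusted p = 0.876). The mitochondrial chromosome, which encodes subunits of the respiratory chain with their ribosomal and transfer RNAs, had 30 tested features, of which 2 were called higher and 5 lower. Its median log2 fold change was -0.33 (camera adjusted p = 0.876), and between -0.761 and -0.063 when 1 library was left out. Without day-15 replicates 1 and 2 the mitochondrial features were called lower, with a median of -1.22 (camera adjusted p = 0.000314). Those 2 libraries hold the highest mitochondrial shares of day 15, so leaving them out favours this call. The median was above 0 with no count filter (0.235) and with the lower title number alone (0.08), while camera's direction stayed down and the set was not called. The rotation test fry, which asks whether a set moves on balance and not whether it differs from other genes, called 10 chromosomes. Classes of genes by exon number did not differ from the other genes either, with 0 of 4 called by camera and 0 at an unadjusted p under 0.05. Single-exon genes included 138 called higher and 130 called lower among 798 tested.

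Expression confined to 1 day by the thresholds used was found for 81 genes at day 8 and 23 genes at day 15. These genes had at least 1 CPM in each library of that day and under 0.1 CPM in each library of the other. Their median levels were 4.23 CPM for the day-8 genes and 7.75 CPM for the day-15 genes, and the highest means were 862 and 84.2 CPM. On chromosome 2, the window from 120000001 to 121000000 held 3 of the day-8 genes, which together summed to 874 ± 136 CPM at day 8 (SD, n = 4) and 0.018 ± 0.0336 CPM at day 15 (SD, n = 7). No other window held 3 or more genes of 1 kind. Without day-15 replicate 1 the number of day-15 genes was 43, and without day-8 replicate 4 it was 41. The rule asks for 7 libraries on at day 15 but 4 at day 8, so 81 and 23 do not compare like with like. With the higher title number alone, which leaves 4 libraries of each day, the numbers were 116 at day 8 and 51 at day 15. Leaving out libraries can only raise or keep such numbers.

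The 10 most abundant genes of each library took 16.7% ± 1.36 of the counts at day 15 (SD, n = 7) and 12.6% ± 0.693 at day 8 (SD, n = 4). This difference passed an exact two-sided permutation test (p = 0.00303, the smallest that 330 splits allow; adjusted p = 0.0121 over 4 measures). Mitochondrial features took 2.29% ± 1.6 of the counts at day 15 (SD, n = 7) and 3.75% ± 0.683 at day 8 (SD, n = 4), which did not pass (exact permutation adjusted p = 0.141). Within day 15, replicates 1 and 2 held 5.08% and 4.08% and the other 5 libraries between 1.13% and 1.79%. Without those 2 libraries the difference was -2.38 percentage points (exact permutation adjusted p = 0.0106). They were left out as a possible batch, but they hold the 2 highest day-15 values of this measure. The remaining day-15 values all lie below the lowest of day 8 (2.8%). The test was therefore bound to pass and gives no independent evidence of a difference. Mitochondrial features under 100 bases, a measure that was not planned, held 0.024% at day 15 and 0.0495% at day 8 (exact permutation adjusted p = 0.109). That difference passed without day-15 replicate 1 (exact permutation adjusted p = 0.019) and without replicates 1 and 2 (exact permutation adjusted p = 0.0106). Replicate 1 had the highest day-15 value of this measure too and replicate 2 the next, so the same limit holds. After thinning, 15580 ± 881 genes had a count at day 15 (SD, n = 7) and 15780 ± 684 at day 8 (SD, n = 4), a difference within the spread (exact permutation adjusted p = 0.773).

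**Figure D4:**
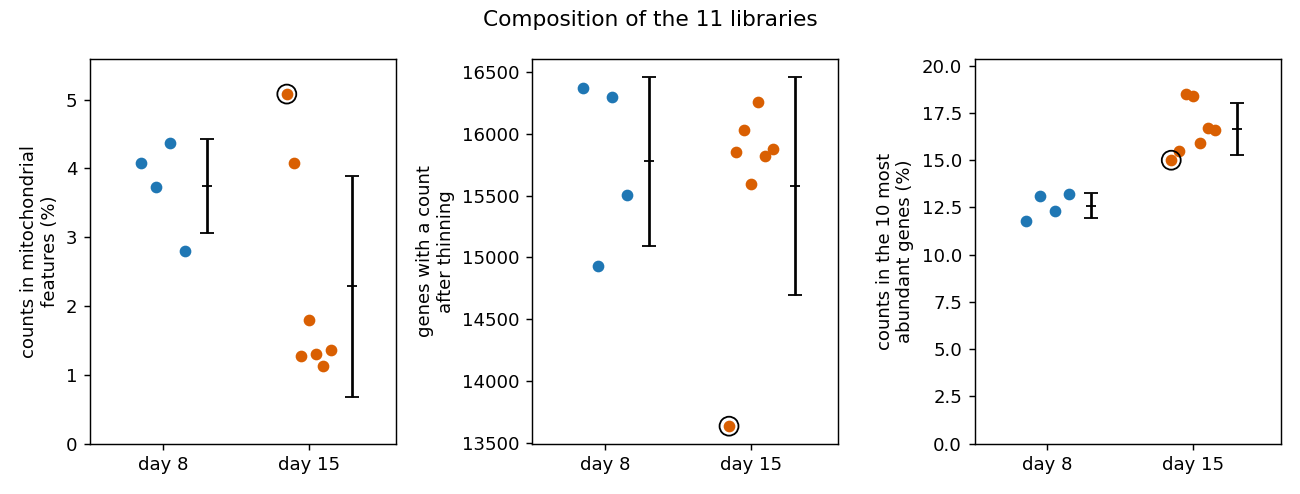
Share of counts in mitochondrial features, genes with a count after thinning and share of counts in the 10 most abundant genes, with 1 point per library, black bars for the mean and SD, and a ring around day-15 replicate 1. The ringed library has 13637 detected genes and 5.08% mitochondrial counts, the lowest and highest values of the 11 libraries.

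Libraries of the higher title number differed from those of the lower one, within day 15, in 0 of 13396 tested genes (edgeR quasi-likelihood test), with 1806 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.316. Limma voom called 0 genes and DESeq2 called 162. Against day 8, libraries of the higher title number alone gave 3047 genes higher and 3186 lower, and those of the lower number alone gave 1904 higher and 1914 lower (edgeR quasi-likelihood test). The 2 libraries without a serial number in their name differed from the other 5 in 2011 genes. With replicate 2 alone on that side 2 genes were called, and with replicate 1 alone 6751 genes (edgeR quasi-likelihood test). In both of these fits the spread comes from the other 5 libraries, and the single library is assumed to vary like them.

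Libraries of 1 day varied by a biological coefficient of variation of 56.7% at day 8 and 59.3% at day 15, over the same 14278 genes. Without replicate 1 the day-15 value was 0.392 as a fraction, against 0.593 with it.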

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

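Of the tests in this part, that of a swapped label was chosen after the result was seen, as were the bound of 1% for admixed tissue and the choice of reference libraries for the length test. The measures were compared within each day by the gap of the most extreme library to its nearest neighbour, over 32 groups of values, of which chance picks about 1 in 20. That rule picked 6 values.

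Day-15 replicate 1 accounted for 4 of them. It had 13637 genes with a count after thinning, where the other day-15 libraries had 15594 to 16255. Its TMM factor was 0.554, where the others had 0.955 to 1.087. Its mean rank correlation with libraries of its day was 0.893, where the others had 0.955 to 0.963. On the second principal component it lay at -187.7, where the others lay between 10.4 and 53.4. These measures are not independent of each other. Day-15 replicate 7 held 92463564 counts, where the other day-15 libraries held 46152663 to 53541972. ENSBTAG00000017531 had 0.354 CPM in day-8 replicate 4 and no count in the other 3 day-8 libraries, a level near the floor.

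What sets day-15 replicate 1 apart is not explained by a label swapped with a day-8 library, since its mean rank correlation with day 8 was 0.781, below the lowest with another day-15 library (0.878). Admixed day-8-like tissue is also excluded as the cause. The 12 genes on at day 8 and near 0 in the other day-15 libraries reached 0.0935% of their day-8 level in it, under the 1% set as a bound, although above the highest other day-15 library (0.0342%). Few captured molecules remain a candidate explanation. Of 740 genes at 1 to 5 CPM in each of the other day-15 libraries, 5.41% had no count in it. For each other library treated the same way the share was 0%, over 350 to 406 genes. Those smaller sets required at least 1 CPM in replicate 1, so the shares do not compare like with like. No gene above 50 CPM in the other day-15 libraries was without a count in replicate 1. A loss of long transcripts also stays open. The deviation of replicate 1 from the others fell with exonic length (rank correlation across genes of -0.319), but replicate 3 came close (-0.275) without standing apart. Replicates 5 and 6 had 0.327 and 0.28 in the other direction, and replicate 1 was measured against a mean that holds them. A biological difference of the conceptus of replicate 1 was not tested.

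The difference between the days gave more called genes than other splits, since 1 of 100 splits, the real one, reached 5600 and the highest other 0. Each other split mixed the days in at least 1 of its groups, so the day difference entered its spread. Their 0 therefore does not measure how many genes chance would call without a day difference. Depth as the cause is excluded, as 99.0% of the called genes remained called in the same direction after thinning. A bias by gene length is excluded as the whole cause, with 93.4% called under the length offset. Under TMM scaling a few abundant genes did not carry the calls, as 98.8% of the others stayed called without the 50 most abundant genes. TMM factors already trim extreme genes, so this test had little room to show such an effect. With library totals alone, 84.4% of the called genes stayed called. RNA extraction, library series and growth in the uterus cannot be told apart from age, because the design changes them together.

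For the chromosomes and the title numbers, the number of calls cannot test chance, because the real split called 0 and no split can call fewer. All 100 splits for the chromosomes and all 35 for the title numbers gave at least that many, and the highest other gave 2 chromosomes and 1 gene. At an unadjusted p under 0.05, the real title numbers gave 1806 genes, and 2 of the 35 splits gave more. The real split and those 2 all hold day-15 replicate 1 in their group of 3, so this rank cannot be told apart from the place of that library. Without replicate 1 the title numbers gave 1282 genes at that level and a smallest adjusted p of 0.0993 (edgeR quasi-likelihood test).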

How the results depend on the processing

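Settings chosen after seeing the data were the length offset, quality weights, removal of mitochondrial or overlapping genes, other window sizes, removal of day-15 replicates 1 and 2, the comparison by library serial number, and those for windows, exon classes, neighbouring genes and genes on at 1 day. No paired analysis was possible because replicate numbers were given in accession order and no label ties a day-8 library to a day-15 library. Alternatives that need gene lists, gene families or GC content were not run. The counts of genes changed stayed within 1.5 times of 2710 and 2890 in other settings, except that glmTreat against 2-fold gave 1035 higher and 1449 lower, since it asks for a larger change, and the lower title number alone gave 1914 lower, where replicate 1 is 1 of 3 day-15 libraries. Leaving out 1 library gave 2115 to 3404 higher and 2494 to 3659 lower. For the title numbers within day 15, DESeq2 called 162 genes and the other settings 0. Chromosomes called were 10 with fry and 1 without day-15 replicates 1 and 2. The X chromosome, not called in any camera setting, had its direction turned with the filter of 5 CPM (median 0.11). The median of mitochondrial features turned to 0.235 with no filter and 0.08 with the lower title number alone, where camera's direction did not turn.

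The windows higher at day 15 (1 as reported) were 2 with library totals, with no filter, with 500 kb windows and without overlapping genes, 188 with fry, and 0 with the 5 CPM filter, without the 50 most abundant genes, with the lower title number alone, without day-15 replicates 1 and 2, with an estimated correlation and with 2 Mb windows. Windows lower (4 as reported) were 289 with fry, 2 without overlapping genes and 1 with 2 Mb windows. They were 0 with the 5 CPM filter, either title number alone and an estimated correlation. Under the 5 CPM filter 2 of the 4 reported windows were not tested, so its 0 is no failed test for them. The other 2 had smaller median falls there, from -2.71 to -1.97 on chromosome 18 and from -4.08 to -1.21 on chromosome 21 (camera adjusted p = 0.428 for both). Without day-15 replicates 1 and 2 none of the 4 stayed called (camera adjusted p of 0.0748 to 0.0995), and 1 other window, of mitochondrial features, was called lower. Leaving out 1 library gave 0 to 2 higher and 0 to 5 lower, and the 0 came without day-15 replicate 1.

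The share of counts in the 10 most abundant genes was higher by 4.66 percentage points with the lower title number alone and 3.57 with the higher (exact permutation adjusted p = 0.114 for both, where few splits limit the test). The mitochondrial share differed by -2.38 points and its features under 100 bases by -0.0356 points without day-15 replicates 1 and 2, and both then passed the test (exact permutation adjusted p = 0.0106). Those 2 libraries hold the highest day-15 values of both measures, so these passes are no independent evidence. Leaving out 1 library gave -1.92 to -1.25 and -0.0321 to -0.0215, and the short features passed without day-15 replicate 1. Genes detected after thinning turned to 198 more at day 15 with the higher title number alone and 130 more without day-15 replicates 1 and 2, came to -697 with the lower title number alone and -795 at a minimum of 5 counts (exact permutation adjusted p = 0.0727), against -195 as reported, and ranged from -473 to 121 when 1 library was left out. With the 5 CPM filter the coefficient of variation was 0.337 at day 8 and 0.498 at day 15. Leaving out 1 library gave 0.517 to 0.604 and 0.392 to 0.622. Genes on at day 15 alone numbered 6 at a minimum of 5 CPM, 51 with the higher title number alone, 46 without day-15 replicates 1 and 2, and 23 to 43 when 1 library was left out. Genes on at day 8 alone numbered 15 at 5 CPM, 139 with the lower title number alone, and 85 to 103 when 1 library was left out. Libraries without a serial number against the others gave 2 to 6751 genes when 1 of them was left out, which leaves a single library on that side, with its spread taken from the other 5. The cause of these moves was not tested where none is named. At the smallest library total, levels under 0.065 CPM are not resolved.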

Other observations

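The groups of genes in this part were formed after the data were first read, and the overlap count for chromosomes 8 and 16 was chosen after the window results were seen. The windows whose summed CPM changed most in absolute terms, with ranges that do not overlap between days, were taken by size. Chromosome 13 from 74000001 to 75000000 went from 1278 ± 222 CPM at day 8 (SD, n = 4) to 58050 ± 15340 CPM at day 15 (SD, n = 7). There 12 genes were called higher and 6 lower, and 1 gene held 83.3% of the day-15 level. On chromosome 29, the window from 39000001 to 40000000 went from 308 ± 33.2 CPM to 26600 ± 11380 CPM, with 4 genes called higher and 0 lower and 97.3% of the level in 1 gene. On the same chromosome, 29000001 to 30000000 went from 1254 ± 261 CPM to 10360 ± 1548 CPM. None of these windows was called by camera (adjusted p of 0.478, 0.114 and 0.41), which weighs each gene alike.

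In the other direction, chromosome 10 from 67000001 to 68000000 went from 11220 ± 774 CPM at day 8 to 1708 ± 389 CPM at day 15, with 96.6% of the day-8 level in 1 gene. Chromosome 29 from 49000001 to 50000000 went from 4814 ± 324 CPM to 403 ± 57.9 CPM, although 3 of its genes were called higher and 3 lower. Chromosome 1 from 127000001 to 128000000 went from 5152 ± 228 CPM to 850 ± 427 CPM, with 98.2% in 1 gene. Camera called none of these (adjusted p of 0.932, 0.929 and 0.852).

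Neighbouring genes were both called, and in the same direction, more often than in shuffled gene orders. Of 14218 neighbouring pairs of tested genes, 1413 were called in the same direction, where 1000 shuffles of the calls within chromosomes gave a mean of 1106 and at most 1181. A chance order of genes is thus excluded as the cause. Reads shared by overlapping genes are excluded as the whole cause, since 1330 of 13261 pairs without overlap were called in the same direction, against at most 1103 in the shuffles. The shuffles moved call and direction together, and pairs called in opposite directions were not counted. A clustering of called genes whatever their direction would therefore raise the number as well, and agreement in direction was not tested alone. Shared regulation of neighbours, or copies of 1 gene lying side by side and sharing reads, may each contribute, and the data at hand do not separate them. Genes are not independent replicates, and the test describes their order, not the libraries.

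For the 5 called windows, 1 of 100 splits of the libraries, the real one, gave as many windows (5, where the highest other split gave 4). The other splits mixed the days, so their numbers are not those of libraries without a day difference. On simulated counts with 8-fold changes between the days, camera also called 2 windows that were not set to change as a whole, so single calls may be false. No window was called with an estimated correlation (adjusted p = 0.978 for each) or without day-15 replicate 1, although without that library the median log2 fold changes moved little (-2.71 to -2.52 on chromosome 18, 3.05 to 3.05 on 8, -3.29 to -3.27 on 9, -6.36 to -6.24 on 16 and -4.08 to -3.92 on 21). The count filter moved some medians more. With the filter of 5 CPM they were -1.97 on 18, -1.21 on 21 and 4.33 on 8, while 9 and 16 were not tested. With no filter the median on 21 was -2.76. The windows on chromosomes 8 and 16 hold 0 tested genes whose spans overlap another gene. In the other 3 windows the genes without overlap kept the direction of the median, as did all 5. On chromosome 9 the median went from -3.29 to -3.30 with 7 of 8 genes left, and the window stayed called (camera adjusted p = 0.0277). On chromosome 18 it went from -2.71 (quartiles -3.73 and -1.04) to -2.68 (-3.09 and -1.51), and on chromosome 21 from -4.08 (-4.76 and -0.65) to -3.56 (-4.96 and -0.11). Those 2 windows lost their call in a test on 15 of 20 and 7 of 13 genes (camera adjusted p = 0.0596 and 0.416), where fewer genes also weaken the test. Reads shared by overlapping genes are thus excluded as the whole cause of the fold changes, and reads shared by near-identical copies were not tested in any window.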
